A study of Homo sapiens with 12 samples.

How the data were processed

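The samples were 22Rv1 prostate cancer xenografts, grown under the skin of immunodeficient mice and treated with zotatifin at 0.3 mg/kg or with its vehicle. Tumours were taken 6 h after treatment. Each of the 4 groups (vehicle or zotatifin, footprints or RNA) had 3 libraries, so that there were 12 libraries and 6 per assay. Footprints came from monosome fractions after digestion with ribonucleases, and fragments between 24 and 34 nt were taken from a gel. RNA libraries came from the same lysates and were made with a stranded total RNA kit.

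Groups were taken from the sample titles and the column names of the count tables, and no column was left without a sample. Per the labels, the treatment field of 6 of the 12 samples contradicts their title: it names zotatifin for every footprint library and no treatment for every RNA library. The titles and the column names were used, and the code number in the column names was read as the development name of zotatifin. The replicate numbers were checked for pairing on 4880 genes with a mean of at least 50 counts, by correlating log2 CPM (prior count 2) after the mean of each group was removed. Footprint and RNA libraries of the same treatment and number correlated at 0.217 to 0.440 (6 pairs), and those with other numbers at −0.381 to 0.119 (12 pairs). Libraries of different treatments with the same number correlated at −0.0936 to 0.182 (6 pairs), against −0.197 to 0.170 for other numbers. The numbers therefore mark tumours within a treatment. These values gave no clear sign that they pair vehicle with zotatifin tumours, though 6 pairs cannot exclude a weak pairing.

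The deposited RNA and footprint tables hold raw counts per transcript, with 19038 transcripts for RNA and 19037 for footprints. In the authors' RNA comparison table, the mean level is a signal in normalised counts, the fold change and its standard error are on the log2 scale, the test statistic is a Wald score, and the p-value comes plain and adjusted. In the authors' footprint comparison table, the treatment estimate is on the natural log scale, and it comes with an FDR, an adjusted p-value of a z test. That scale was read from the values: over 1566 genes with a mean above 200 counts in both assays, the estimate had weights of 0.665 on the log2 footprint change and −0.666 on the log2 RNA change, where the natural log of 2 is 0.693. The estimate was therefore taken as a change of translational efficiency (TE, footprints relative to RNA). Per the submitters' processing notes, the upstream tools were cutadapt 2.3, UMI-tools, Bowtie2 2.3.5 and DESeq2, on the hg38 build. The order of these steps, the strand setting and the part of the transcript that was counted are not given in the sources used here. Each gene has 1 transcript in the tables, apart from 11 symbols found on more than 1 transcript. Of 19027 symbols, 18953 matched a RefSeq symbol or synonym, from which the GRCh38.p14 positions were taken.

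All tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the quasi-likelihood F test with robust dispersions was applied to zotatifin against vehicle, in footprints and in RNA apart. Change of TE was tested as the interaction of assay and treatment in 1 model over the 12 libraries, with TMM within each assay and genes that passed the filter in both. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and "adjusted p" for a gene is always this value. Fold changes are log2 with their standard error, zotatifin over vehicle, and levels are TMM-scaled CPM with the SD over 3 libraries. The level of TE is the log2 ratio of footprint to RNA CPM. Because the numbers mark tumours, the TE model was also fitted with the tumour as a block.

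Gene groups were 28 lists fixed before the data were examined, 21 of pathways and 7 of markers for other cell types, tumour state or RNA quality. Each list with at least 3 tested members was tested with camera in limma 3.58.1 with an inter-gene correlation of 0.01, and adjusted over the lists of 1 comparison. This preset correlation is a strong assumption: with an estimated correlation, 0 of the 25 tested lists passed in any of the 3 comparisons. The p values with an estimated correlation stand beside each list that camera called. Member counts are given over all tested genes and adjusted over the list alone. No mitochondrially encoded protein and no noncoding RNA of the quality list is in the tables, and 0 (footprints), 2 (RNA) and 0 (TE) endothelial markers passed the filter, so these 3 lists were not tested with all libraries.

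Genes were named by a rule written before the data were examined. It takes, per comparison, the 10 largest rises and the 10 largest falls among calls with a mean of at least 20 counts per library (for TE in each assay) and, for footprints and RNA, no overlap between the treatments. It adds 16 genes chosen in advance and the 4 members of each list with the smallest p. The rule gave 256 genes, of which 255 have a position.

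Footprint libraries held 838135 to 2013968 counts and RNA libraries 5761921 to 8153674. The biological coefficient of variation was 9.20% for footprints, 13.6% for RNA and 11.4% for the joint model. Between replicates, the chi-square per degree of freedom over genes was 1.75 to 2.72 in footprints and 6.29 to 19.6 in RNA, so that spread exceeded counting error. It was highest in the pairs with zotatifin RNA library 2 (14.5 and 19.6), which stood further from its replicates than the other RNA libraries did. Replicates correlated in log2 CPM at 0.967 to 0.987. The models were tested on simulated data with planted changes. For a planted log2 change of 1.5, they recovered 92% of genes in footprints, 95% in RNA and 75% in TE (84% with the tumour block). For a planted change of 0.8, they recovered 74%, 67%, 34% and 57%. The share of false calls was 5.14%, 6.90%, 8.40% and 5.37%. The p-values measure the spread between samples that the labels call biological replicates. In TE without the block, they treat the footprint and RNA libraries of a tumour as independent.

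Alternatives were RLE, upper-quartile and library-total scaling, no filter or a stricter filter (1 CPM and 20 counts in 3 libraries), DESeq2 1.42.0, limma-voom with and without group weights, replicate blocks, other thresholds, camera with an estimated correlation, fry, and leaving out each library or tumour. Thinned footprints and the removal of genes in the top 5% of the vehicle ratio of footprints to RNA (for footprints also of those that did not pass the RNA filter) were chosen after the data were seen. A planned study of 5′ UTR sequence was not run, since no transcript sequence was used here. No mouse reference was used, so reads of mouse cells that match human transcripts were not removed here. Histone genes, FAM72A and FAM72C, HBG1 and ACTBL2 have close paralogs, between which reads cannot be assigned with certainty. Some genes and gene lists of the plan are not reported here.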

Results

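Ribosome footprints and RNA were sequenced from 22Rv1 xenografts, tumours of a human prostate cancer cell line grown in mice, 6 h after an injection of zotatifin or vehicle. Zotatifin inhibits eIF4A, the helicase that unwinds mRNA leaders for the scanning ribosome. There were 12 libraries in 4 groups of 3. RNA libraries held 5761921 to 7121802 counts with vehicle and 6594884 to 8153674 with zotatifin. Footprint libraries held 1592316 to 2013968 counts with vehicle and 838135 to 1540867 with zotatifin (n = 3 each). The mean of the footprint totals with zotatifin stood at 0.653 of that with vehicle (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 can give), and the RNA totals at 1.16 (p = 0.2, exact permutation test). All values are relative to the library, so a change shared by all mRNAs cannot be seen in them. The first principal component held 41.6% of the variance in RNA and 53.1% in footprints, and it separated the treatments in both.

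The footprint comparison asks which mRNAs carried more or fewer ribosomes after zotatifin, relative to the others. Of 9544 genes tested, 307 rose and 374 fell (681 in all), and 46 of the rises and 63 of the falls were larger than 2-fold. The largest rise was that of SIPA1L3, a regulator of cell polarity (transcript ENST00000222345, chromosome 19, 37907208 to 38208369, GRCh38.p14), whose footprints went from 20.0 ± 0.497 to 203 ± 66.7 CPM (SD, n = 3 each; log2 change 3.33 ± 0.24, SE, adjusted p = 3.7e-06). FOXO1, a transcription factor held in check by insulin signalling (chromosome 13, 40555667 to 40666641), rose from 69.1 ± 1.84 to 250 ± 40.3 CPM (1.84 ± 0.13, adjusted p = 1.5e-10). CARM1, an arginine methyltransferase that acts as a coactivator of steroid receptors (chromosome 19, 10871553 to 10923075), rose from 192 ± 21.3 to 517 ± 108 CPM (1.42 ± 0.13, adjusted p = 3.4e-08). The other 7 of the 10 largest rises were ONECUT3 (2.14), LOR (1.71), STUM (1.70), HOXC12 (1.61), IFFO2 (1.42), BOD1L2 (1.36) and LMO2 (1.32). These 10 calls held without any 1 of the 6 libraries. LOR, STUM and BOD1L2 did not pass the RNA filter, so no TE was tested for them.

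Among the 10 largest falls were the matrix genes FBN1 (−1.97), COL3A1 (−1.92), COL1A1 (−1.79) and COL1A2 (−1.48), and the endocytic receptor LRP1 (−1.92). RNA of these genes was lower as well in the authors' comparison. Its log2 changes were −1.83 for FBN1, −1.55 for COL3A1, −1.48 for COL1A1, −1.88 for COL1A2 and −1.61 for LRP1. The authors' TE changes for them ran from −0.27 (LRP1) to 0.57 (COL1A2) on the log2 scale. Footprints of COL1A1, a chain of fibrillar collagen (chromosome 17, 50184101 to 50201631), fell from 205 ± 59.9 to 60.8 ± 18.9 CPM (SD, n = 3; log2 change −1.79 ± 0.33, SE, adjusted p = 0.030). Syndecan SDC2 (chromosome 8, 96493813 to 96611790) fell from 29.7 ± 6.28 to 9.46 ± 3.79 CPM (−1.54 ± 0.28, adjusted p = 0.0010). QKI, an RNA-binding regulator of splicing (chromosome 6, 163414718 to 163578592), fell from 60.1 ± 13.8 to 22.5 ± 3.04 CPM (−1.40 ± 0.20, adjusted p = 7.8e-05). The remaining falls were those of reads counted for the globins HBE1 (−1.59) and HBG1 (−1.51) and for the vesicle fusion gene STX16 (−1.44). HBG1 did not pass the RNA filter. Reads of mouse cells were not removed, so globin and matrix footprints may come from the mouse. In all 20 genes, the 3 zotatifin libraries lay apart from the 3 vehicle libraries, as the rule for naming them required. The calls for SDC2 and QKI held without any 1 library. The other 8 falls were lost without at least 1: the adjusted p went up to 0.219 for FBN1 (without vehicle library 1 or zotatifin library 2 or 3), 0.109 for COL3A1 (zotatifin library 2), 0.257 for LRP1 (vehicle library 1 or any zotatifin library), 0.179 for COL1A1 (vehicle library 1 or zotatifin library 2), 0.187 for COL1A2 (zotatifin library 2 or 3) and 0.0745 for STX16 (vehicle library 1 or zotatifin library 3). For HBE1 and HBG1 it went up to 0.116 and 0.204 (vehicle library 1 or zotatifin library 1 or 2).

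The count of 681 fell to 185 without vehicle library 1, 415 without vehicle library 3 and 438 without zotatifin library 1. DESeq2, run with its own filter and so on another set of genes, gave 418. Of 74 named footprint calls, 34 held without any 1 library.

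**Figure D1:**
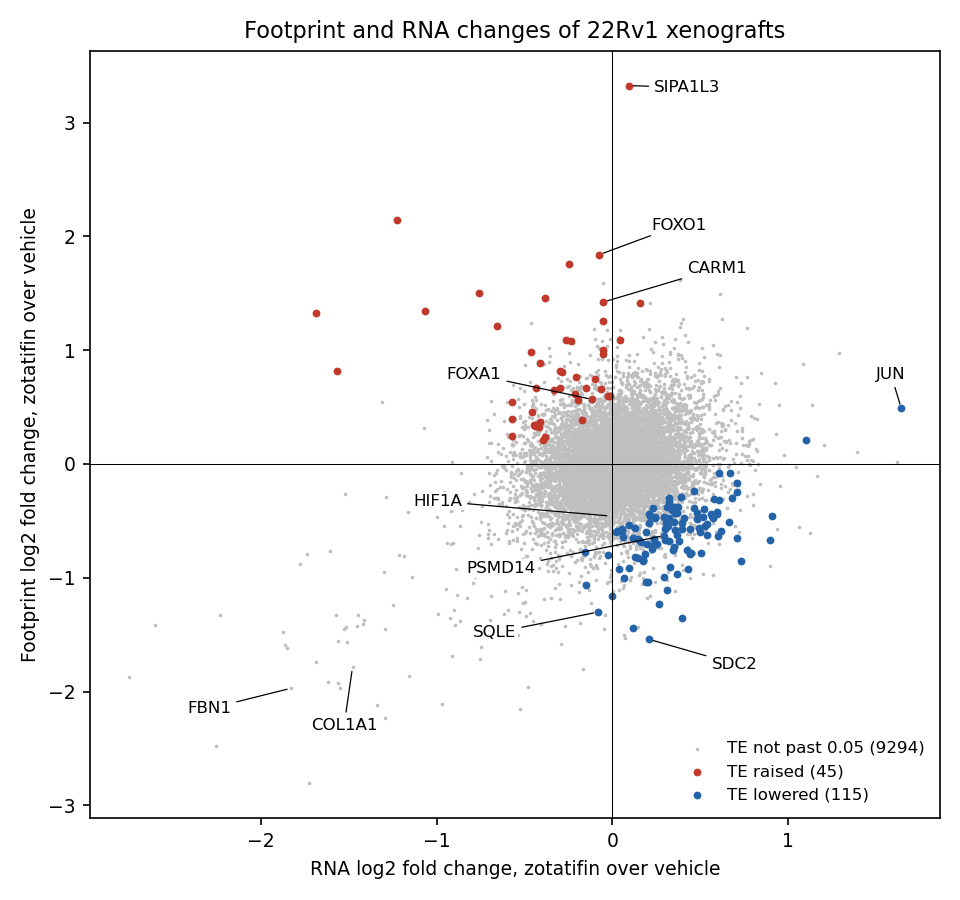
Log2 fold change of RNA (horizontal axis) against that of footprints (vertical axis), zotatifin over vehicle, for 9454 genes, 1 point per gene (n = 3 libraries per group and assay). Genes with raised TE (45, red) lie above the cloud, with SIPA1L3 highest at 3.33, and genes with lowered TE (115, blue) lie mostly to the lower right, where 110 have a positive RNA change.

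Footprints of replication-dependent histones, which package new DNA in S phase, rose in 27 of 48 genes and fell in 0 (35 and 0 adjusted over the list alone). The median log2 change was 0.40 (camera, adjusted p = 1.3e-20; adjusted p = 0.505 with an estimated correlation). The linker histone HIST1H1E rose from 1256 ± 58.5 to 1826 ± 158 CPM (0.54 ± 0.10, adjusted p = 0.0015), and HIST1H2AJ (0.58), HIST1H2AI (0.57) and HIST1H2BK (0.53) rose alike, each also without any 1 library. Histone genes share near-identical coding sequences, so a footprint may not belong to the gene it was counted for. Of 78 cytosolic ribosomal proteins, 6 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 7.6e-06; adjusted p = 0.797 with an estimated correlation). RPS2 rose from 566 ± 45.6 to 854 ± 141 CPM (0.59 ± 0.11, adjusted p = 0.0015). RPL3 (0.47), RPL8 (0.44) and RPL13 (0.42) also rose, and each of these 3 calls was lost without vehicle library 1 (adjusted p = 0.0677, 0.104 and 0.117). Of 70 nuclear-encoded subunits of oxidative phosphorylation, 4 rose and 1 fell (11 and 3 adjusted over the list alone), with a median of 0.092 (adjusted p = 0.016; adjusted p = 0.797 with an estimated correlation). That list was not called without vehicle library 3 (adjusted p = 0.205) or zotatifin library 2 (0.335). Fibroblast markers (median −1.08) and myeloid markers (mean −2.08) were lower in the same zotatifin libraries in which these 3 lists were higher.

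Of 21 immediate early genes, which respond to growth signals and stress, 2 rose in footprints and 0 fell (3 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.040; adjusted p = 0.521 with an estimated correlation). IER2 rose by 0.67 ± 0.14 (adjusted p = 0.0039), also without any 1 library, and JUND by 0.57 ± 0.16 (adjusted p = 0.031). The JUND call was lost without vehicle library 1 or 3 or zotatifin library 2 or 3 (adjusted p up to 0.147), and that of the list without vehicle library 1 (0.0625) or zotatifin library 2 (0.130). None of 5 neuroendocrine markers rose or fell by its own test, while the list shifted upward (median 0.16, adjusted p = 0.042; adjusted p = 0.505 with an estimated correlation). The shift was lost without vehicle library 1 (0.0693), vehicle library 2 (0.0894) or zotatifin library 3 (0.0507). Both lists moved in the same zotatifin libraries in which fibroblast markers (median −1.08) and myeloid markers (mean −2.08) were lower.

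Footprints of chaperones of the endoplasmic reticulum (ER) and other genes of the unfolded protein response fell in 8 of 21 genes and rose in 0 (12 fell and 1 rose adjusted over the list alone). The median was −0.43 (adjusted p = 2.9e-08; adjusted p = 0.505 with an estimated correlation). HSPA5, the main chaperone of the ER lumen, fell from 1668 ± 216 to 1066 ± 169 CPM (−0.65 ± 0.12, adjusted p = 0.0010). HERPUD1, a part of ER-associated degradation, changed by −0.86 ± 0.14 (adjusted p = 5.0e-04), and MANF by −0.53 ± 0.11 (adjusted p = 0.0035). Of 18 cytosolic heat shock proteins, 6 fell and 0 rose (6 and 0 adjusted over the list alone; median −0.13, adjusted p = 8.9e-04; adjusted p = 0.565 with an estimated correlation). Among them were HSPH1 (−0.91 ± 0.13, adjusted p = 5.7e-05) and the constitutive HSPA8, from 3985 ± 219 to 2456 ± 399 CPM (−0.70 ± 0.11, adjusted p = 3.3e-04). Of 26 genes of cholesterol and fatty acid synthesis, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median −0.22, adjusted p = 0.0016; adjusted p = 0.505 with an estimated correlation). SQLE, the squalene epoxidase of the sterol pathway, fell from 54.0 ± 5.00 to 22.3 ± 3.64 CPM (−1.30 ± 0.19, adjusted p = 9.4e-05). The sterol enzyme MSMO1 (−0.60) fell as well. Each gene named for these 3 lists kept its call without any 1 library, as did the 3 lists. Fibroblast markers were lower in the same zotatifin libraries, with a median of −1.08.

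Some markers of stromal cells fell in footprints, from which reads of mouse cells were not removed. Of 10 fibroblast markers, 4 fell and 0 rose (6 and 0 adjusted over the list alone; median −1.08, adjusted p = 3.5e-10; adjusted p = 0.505 with an estimated correlation). SPARC, a matrix glycoprotein, fell from 65.9 ± 10.4 to 29.6 ± 10.9 CPM (−1.24 ± 0.20, adjusted p = 4.2e-04), also without any 1 library. Of 7 myeloid markers, 2 fell and 0 rose (5 and 0 adjusted over the list alone; mean −2.08, adjusted p = 3.3e-06; adjusted p = 0.505 with an estimated correlation). PTPRC, the leukocyte antigen CD45, had 12 to 45 counts per vehicle library and 1 to 2 per zotatifin library (adjusted p = 0.0016). CSF1R fell by 1.42 on the log2 scale (adjusted p = 0.045), a call that was lost without any 1 of the 6 libraries (adjusted p up to 0.181). None of 6 muscle and adipocyte markers (median −0.53, adjusted p = 0.555) and none of 4 red blood cell markers (median −0.57, adjusted p = 0.493) rose or fell. Without vehicle library 3 the muscle and adipocyte list was called (adjusted p = 0.0073), and without vehicle library 2 the red blood cell list (0.011). The direction of the former turned upward without vehicle library 2 (0.408) or zotatifin library 3 (0.586), and that of the latter without vehicle library 1 (0.890).

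Of the other lists reported here, none was called in footprints. Of 27 oncogenes reported to depend on eIF4A, 3 fell and 0 rose (3 and 0 adjusted over the list alone; median 0.019 but mean −0.064, adjusted p = 0.546). These were ODC1, the first enzyme of polyamine synthesis (−0.63 ± 0.11, adjusted p = 0.0010, also without any 1 library), ADAM10 (−0.81, lost without zotatifin library 3, adjusted p = 0.0745) and MDM2 (−0.49, lost without vehicle library 1 or zotatifin library 1, up to 0.116). Of 26 initiation factors, 2 rose and 2 fell (3 and 6 adjusted over the list alone; median 0.00054 but mean −0.044, adjusted p = 0.555), among them EIF4A2, a paralog of the drug target. Of 21 genes of HIF1A and its targets, 2 fell, HIF1A and BNIP3 (−0.63, lost without vehicle library 1 or 3 or zotatifin library 1 or 2, up to 0.158), with a median of −0.14 (adjusted p = 0.236). The HIF1A list was called without vehicle library 1 (adjusted p = 0.013) or vehicle library 2 (0.032), and without vehicle library 3 its direction turned upward (0.725).

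For 8 more lists, few members moved. Footprints rose in 1 and fell in 0 of 20 elongation factors and other TOP mRNAs (median 0.11, adjusted p = 0.511). They rose in 2 and fell in 0 of 26 targets of ATF4 in the integrated stress response (0.097, adjusted p = 0.290). Of 21 p53 targets, 1 rose and 1 fell (median −0.074 but mean 0.0043, adjusted p = 0.991). None of 34 mitosis genes (0.024, adjusted p = 0.759) and none of 9 interferon and inflammatory genes (0.019, adjusted p = 0.759) rose or fell by edgeR, which gives no claim that they stayed level. Of 38 DNA replication genes, 2 rose (CDT1 0.62, POLD1 0.62) and 1 fell (GINS1 −0.72, also without any 1 library), with a median of 0.012 (adjusted p = 0.561). CDT1 was lost without vehicle library 1 (adjusted p = 0.0792), and POLD1 without vehicle library 1 or zotatifin library 1 (up to 0.0594). Of 33 DNA repair genes, 0 rose and 1 fell (median −0.088, adjusted p = 0.246). Of 31 proteasome subunits, 1 rose and 3 fell (−0.048, adjusted p = 0.236).

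**Figure D2:**
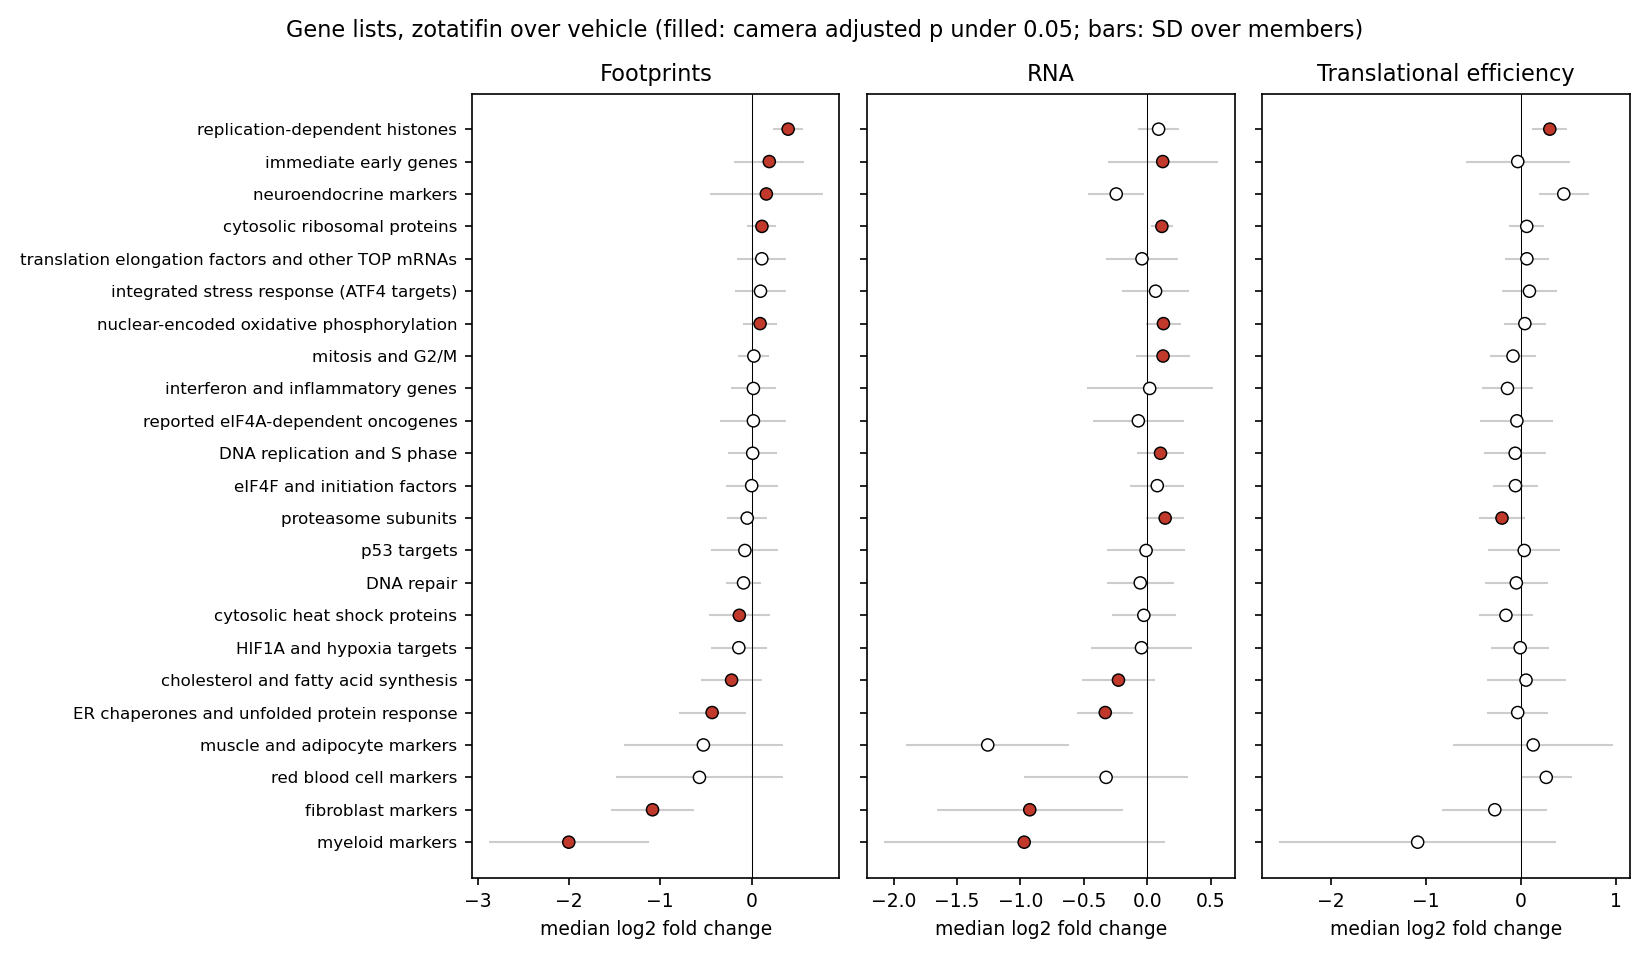
Median log2 fold change, zotatifin over vehicle, of the members of 23 gene lists (vertical axis) in footprints, RNA and TE; points are medians, bars the SD over member genes, and filled points mark a camera adjusted p under 0.05. Histones lie at 0.40 in footprints and 0.30 in TE, ER chaperones at −0.43 in footprints and −0.33 in RNA, and fibroblast markers at −1.08 and −0.93.

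The RNA comparison asks which mRNAs changed in level by 6 h. Of 13118 genes tested, 106 rose and 119 fell (225 in all), and 6 of the rises and 50 of the falls were larger than 2-fold. RNA of JUN, a subunit of the AP-1 transcription factor (ENST00000371222, chromosome 1, 58780791 to 58784047), rose from 120 ± 14.9 to 375 ± 79.2 CPM (SD, n = 3; log2 change 1.64 ± 0.15, SE, adjusted p = 1.9e-06). The homeobox gene IRX3 (chromosome 16, 54283304 to 54286787) rose from 242 ± 30.6 to 520 ± 50.1 CPM (1.11 ± 0.13, adjusted p = 1.3e-04). The growth factor TGFB3 (1.21), ZNF174 (1.29) and TSC22D4 (0.83) rose as well, and these 5 calls held without any 1 library. The other 5 of the 10 largest rises were TGIF1 (1.39), SMOX (1.17), SMAD1 (0.91), PRIMPOL (0.90) and ARMCX6 (0.84). They were lost without at least 1 library each, with adjusted p up to 0.0838 (TGIF1, vehicle library 1), 0.133 (SMOX, vehicle library 1 or any zotatifin library), 0.0911 (SMAD1, vehicle library 1 or 3 or zotatifin library 3), 0.0906 (PRIMPOL, vehicle library 3 or zotatifin library 1 or 3) and 0.200 (ARMCX6, all but vehicle library 2).

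Among the 10 largest RNA falls, COL1A2 went from 44.3 ± 10.6 to 12.1 ± 4.25 CPM (−1.88 ± 0.22, adjusted p = 1.3e-04) and FBN1 from 25.9 ± 8.49 to 7.27 ± 1.45 CPM (−1.83 ± 0.24, adjusted p = 3.1e-04), and these calls held without any 1 library. The other 8 were RASSF4 (−2.62), ACTBL2 (−2.23), CYTH4 (−2.09), IRAK3 (−1.98), CELF2 (−1.85), POU2F2 (−1.81), ZBTB18 (−1.80) and COL5A1 (−1.78), of which several are known from blood cells or matrix. They had 5.57 to 8.93 CPM with vehicle. As in footprints, reads of mouse cells were not removed, so RNA reads of matrix and blood cell genes may come from the mouse. All 8 were lost without vehicle library 1, and all but COL5A1 also without vehicle library 3 and zotatifin library 3, with adjusted p up to 0.0681 for COL5A1, 0.141 for RASSF4, 0.105 for ACTBL2, 0.133 for CYTH4, 0.160 for IRAK3, 0.203 for CELF2, 0.243 for POU2F2 and 0.159 for ZBTB18. CYTH4 and IRAK3 were lost without zotatifin library 1 as well, CELF2 without zotatifin library 2, and POU2F2 without both of these.

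The RNA count depended strongly on single libraries. It was 11 without vehicle library 1, 396 without vehicle library 2, 25 without vehicle library 3, 56 without zotatifin library 1 and 48 without zotatifin library 3, and with no low-count filter it was 624.

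In RNA, 3 of 22 genes of the unfolded protein response fell and 0 rose (10 and 0 adjusted over the list alone; median −0.33, adjusted p = 4.6e-08; adjusted p = 0.425 with an estimated correlation). HSPA5 RNA fell from 646 ± 32.5 to 395 ± 44.0 CPM (−0.71 ± 0.12, adjusted p = 0.0064), alongside SYVN1 (−0.60) and HYOU1 (−0.51). Of 27 cholesterol and fatty acid genes, 3 fell and 0 rose (6 fell and 1 rose adjusted over the list alone; median −0.23, adjusted p = 6.3e-04; adjusted p = 0.868 with an estimated correlation), with INSIG1 (−0.71) and SC5D (−0.58) among them. That list was not called without vehicle library 2 (adjusted p = 0.0754). Each of these 5 genes lost its call without vehicle library 1, and most also without others: HSPA5, SYVN1, HYOU1 and SC5D without vehicle library 3, all of these and INSIG1 without zotatifin library 3, HYOU1 and INSIG1 without vehicle library 2, and SYVN1 and SC5D without zotatifin library 1 (adjusted p up to 0.0681 for HSPA5, 0.131 for SYVN1, 0.194 for HYOU1, 0.119 for INSIG1 and 0.165 for SC5D). Without 1 library, the log2 change ran from −0.78 to −0.62 for HSPA5 and from −0.65 to −0.58 for SYVN1. It ran from −0.65 to −0.42 for HYOU1, −0.85 to −0.53 for INSIG1 and −0.65 to −0.53 for SC5D. All 5 stayed negative, and a fit with 1 library fewer also has less power. Fibroblast markers fell in the same libraries, 4 of 10 (6 adjusted over the list alone; median −0.93, adjusted p = 6.2e-08; adjusted p = 0.425 with an estimated correlation). Myeloid markers fell in 2 of 5 (2 adjusted over the list alone; median −0.97, adjusted p = 0.0029; adjusted p = 0.842 with an estimated correlation). Endothelial markers had too few members in RNA with all libraries, and were called downward without vehicle library 1 (adjusted p = 0.0075) or zotatifin library 2 (0.039).

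Of 28 immediate early genes, 3 rose in RNA and 0 fell (8 rose and 1 fell adjusted over the list alone; median 0.12, adjusted p = 0.0023; adjusted p = 0.445 with an estimated correlation): JUN, IER2 (0.61) and IER5 (0.60). The IER2 call was lost without vehicle library 1 or 3 or zotatifin library 1 (adjusted p up to 0.119), and that of IER5 without any library but vehicle library 2 (up to 0.130). Small upward shifts were called in 5 further lists. Ribosomal proteins had a median of 0.11 (0 of 78 rose by edgeR, 0 adjusted over the list alone; adjusted p = 0.0023; adjusted p = 0.921 with an estimated correlation). Oxidative phosphorylation had 0.13 (0 of 70 rose, 0 adjusted over the list alone; adjusted p = 0.0023; adjusted p = 0.921 with an estimated correlation). Proteasome subunits had 0.14 (0 of 31 rose, 0 adjusted over the list alone; adjusted p = 0.0029; adjusted p = 0.921 with an estimated correlation). Mitosis genes had 0.12 (1 of 34 rose, 1 adjusted over the list alone, the spindle factor TPX2 at 0.61; adjusted p = 0.013; adjusted p = 0.921 with an estimated correlation). DNA replication genes had 0.10 (0 of 38 rose, 0 adjusted over the list alone; adjusted p = 0.022; adjusted p = 0.921 with an estimated correlation). Each of these 5 calls was lost without some library. Without zotatifin library 2 the adjusted p was 0.169 for ribosomal proteins, with the direction turned, 0.981 for oxidative phosphorylation and 0.118 for the proteasome. Without vehicle library 1 it was 0.0763 for oxidative phosphorylation, 0.273 for the proteasome and 0.273 for replication. It was 0.218 for mitosis without vehicle library 3, and without zotatifin library 3 it was 0.135 for mitosis and 0.0767 for replication. The histone list was not called in RNA (median 0.089, adjusted p = 0.17), and its direction hung on single libraries: up without vehicle library 2 (adjusted p = 0.0016), zotatifin library 1 (2.0e-05) or zotatifin library 3 (0.0058), and down without zotatifin library 2 (0.0084). TPX2 itself was lost without vehicle library 1 or 3 or zotatifin library 3 (up to 0.105).

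The TE comparison asks which mRNAs changed in footprints beyond their change in RNA. Without a tumour block, 45 of 9454 genes tested rose and 115 fell (160 in all). That model ignores that the footprint and RNA libraries of a tumour are paired. TE calls below come from it unless the block or the authors are named. With the tumour as a block, 342 rose and 477 fell (819 in all), and 159 of the 160 genes were called with the same sign. TE of SIPA1L3 rose by 3.26 ± 0.32 (SE, adjusted p = 1.7e-05; with the tumour block 3.25, adjusted p = 0.016), while its RNA changed by 0.10. FOXO1 rose by 1.95 ± 0.22 (adjusted p = 1.1e-05; block 1.92, adjusted p = 1.1e-09) and that of CARM1 2.84-fold (adjusted p = 8.2e-05; block 1.49 on the log2 scale, adjusted p = 3.8e-05). The other 7 of the 10 largest rises were LMO2 (3.04), MTRNR2L5 (2.44), TCF7L1 (1.92), GDF11 (1.48), AMMECR1 (1.39), PLEKHA7 (1.35) and the insulin receptor substrate IRS2 (1.35). RefSeq lists MTRNR2L5 as a pseudogene, so its value need not reflect translation of an mRNA. The largest fall was that of SDC2 (−1.72 ± 0.36, adjusted p = 0.0088; block −1.74, adjusted p = 4.4e-05), followed by FAM72C (−1.56), STX16 (−1.54), PRIMPOL (−1.54), ANKRD50 (−1.47), GPBP1 (−1.39), SMAD1 (−1.34), PAFAH1B1 (−1.33), FAM72A (−1.33) and CAB39 (−1.30). PAFAH1B1, a regulator of dynein, went from a log2 ratio of footprints to RNA of 0.36 ± 0.224 to −1.02 ± 0.0829 (SD, n = 3; adjusted p = 8.2e-05). Of these 20 calls, 11 held without any 1 tumour. The others were lost with adjusted p up to 0.0613 (PLEKHA7, vehicle tumour 1), 0.133 (IRS2, vehicle tumour 1 or zotatifin tumour 3), 0.0562 (SDC2, vehicle tumour 1 or zotatifin tumour 2), 0.128 (FAM72C, vehicle tumour 3 or zotatifin tumour 3), 0.240 (STX16, all but zotatifin tumour 2), 0.0730 (ANKRD50, zotatifin tumour 1 or 3), 0.0665 (GPBP1, zotatifin tumour 1), 0.0871 (SMAD1, vehicle tumour 2 or 3 or zotatifin tumour 1) and 0.0778 (FAM72A, vehicle tumour 1 or 3 or zotatifin tumour 1 or 3).

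The TE count was 56 without vehicle tumour 1, 76 without vehicle tumour 2, 57 without vehicle tumour 3, 61 without zotatifin tumour 1 and 95 without zotatifin tumour 3. For an effect of 0.8 the model without the block had low power, since it recovered 34% of planted changes of that size. With the block, 57% were recovered. The simulated data for the model without the block held no difference between tumours of a treatment.

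Among the fixed lists, TE of replication-dependent histones shifted upward, with 42 of 44 members above 0 and a median of 0.30 (adjusted p = 2.6e-08; adjusted p = 0.909 with an estimated correlation; tumour block, adjusted p = 6.2e-18). In edgeR without the block, 0 of 44 histone genes passed (0 adjusted over the list alone, 13 at an unadjusted p under 0.05), and with the tumour block 16 rose and 0 fell. TE of proteasome subunits shifted downward, with 24 of 31 members below 0 and a median of −0.20 (adjusted p = 0.0058; adjusted p = 0.909 with an estimated correlation; tumour block, adjusted p = 0.0033). Of these, 1 fell (2 adjusted over the list alone; with the tumour block 4 fell and 1 rose): PSMD14, the deubiquitinase of the lid (−0.89 ± 0.17, adjusted p = 0.0050, also without any 1 tumour). The proteasome shift was lost without vehicle tumour 1 (adjusted p = 0.106) or zotatifin tumour 2 (0.155). Footprints of these subunits had a median of only −0.048 (camera, adjusted p = 0.236), while their RNA had one of 0.14, with 26 of 31 above 0. The TE shift thus goes more with higher RNA than with fewer footprints. That RNA shift was lost without the RNA libraries of the same tumours. Ribosomal proteins (median 0.062, adjusted p = 0.273) and TOP mRNAs (0.063, adjusted p = 0.235) were called without vehicle tumour 2 (adjusted p = 0.0024 and 0.016) or zotatifin tumour 2 (5.5e-08 and 0.0026). Of the cholesterol and fatty acid genes, SQLE fell (−1.19 ± 0.25, adjusted p = 0.0091) and SREBF1, the transcription factor of lipid synthesis, rose (0.65 ± 0.16, adjusted p = 0.027), so that 1 of 26 rose and 1 fell (3 and 3 adjusted over the list alone, and 3 and 3 with the tumour block). SQLE was lost without vehicle tumour 3 (adjusted p = 0.0775), and SREBF1 without any tumour but zotatifin tumour 2 (up to 0.123).

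**Figure D3:**
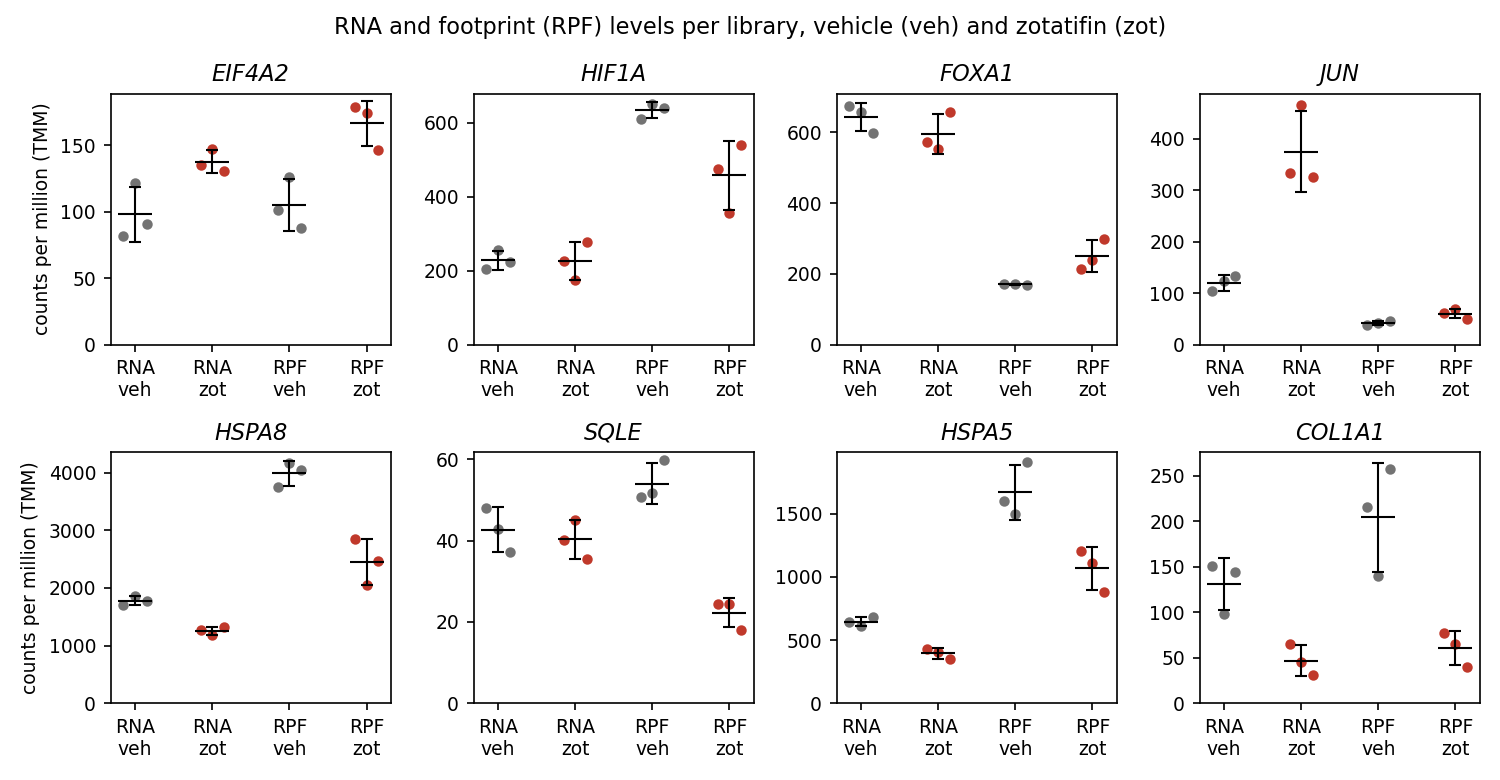
TMM-scaled CPM (vertical axis) of RNA and footprints (RPF) of 8 genes in vehicle (grey) and zotatifin (red) tumours; points are libraries, bars the mean and SD (n = 3). RNA of JUN rises from 120 to 375 CPM, and footprints drop from 54.0 to 22.3 CPM for SQLE and from 1668 to 1066 CPM for HSPA5.

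The genes chosen in advance for this drug and tumour were mixed. HIF1A, the oxygen-regulated transcription factor (chromosome 14, 61695513 to 61748258), fell in footprints from 633 ± 21.2 to 457 ± 93.6 CPM (−0.46 ± 0.12, adjusted p = 0.015), a call lost without vehicle library 1 or zotatifin library 2 (adjusted p up to 0.0732). Its RNA changed by −0.0074 (adjusted p = 0.98), and its TE by −0.42 ± 0.20 (adjusted p = 0.31), which passed with the tumour block (−0.44, adjusted p = 0.0073). The pioneer factor FOXA1 rose in footprints from 170 ± 0.665 to 251 ± 44.2 CPM (0.57 ± 0.12, adjusted p = 0.0035; lost without zotatifin library 3, 0.0552). Its TE rose by 0.71 ± 0.17 (adjusted p = 0.027; block 0.70, adjusted p = 1.1e-04), a call lost without any tumour but zotatifin tumour 2 (up to 0.154). EIF4A2 footprints rose by 0.65 ± 0.13 (adjusted p = 0.0032), also without any 1 library, and its RNA changed by 0.49 (adjusted p = 0.066). MYC, CCND1, EIF4A1, EIF4E, EIF4G1, MCL1, HOXB13, KLK3, KLK2, TMPRSS2, ATF4 and VEGFA passed in none of the 3 comparisons. Their footprint changes ran from −0.34 (VEGFA, adjusted p = 0.62) to 0.46 (HOXB13, adjusted p = 0.052), with 0.18 for MYC (adjusted p = 0.40) and 0.22 for CCND1 (adjusted p = 0.19). In the authors' RNA comparison with DESeq2, HOXB13 was called as raised (0.43, adjusted p = 0.0061), as was EIF4A2 (0.49, adjusted p = 0.045). The authors' TE comparison called HIF1A as lowered (−0.46 on the log2 scale, z test, FDR 2.3e-13) and FOXA1 as raised (0.73, FDR 2.4e-17). Its model is not described in the sources used here, and it called far more genes.

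Over the 9454 genes tested in all 3 comparisons, the log2 changes had a Spearman correlation of 0.168 and a Pearson correlation of 0.243 across genes, which are not independent replicates. The Spearman correlation was 0.121 without vehicle tumour 1 and 0.233 without vehicle tumour 2. Of 656 genes changed in footprints, 622 did not pass in RNA, 25 changed the same way and 9 the opposite way. Both assays rose in 10 genes and fell in 15, where independence of the calls would give 3.04 and 2.59. Of the 115 genes with lowered TE, 110 had a positive RNA change, 25 of them past the threshold, and 32 did not pass in footprints. JUN is of this kind: its RNA rose 3.13-fold, its footprints changed by 0.49 (adjusted p = 0.066), and its TE fell by 1.12 on the log2 scale (SE 0.23, adjusted p = 0.0080; lost without vehicle tumour 1, 0.0562). RNA enters TE as the denominator, so noise in RNA moves both values in opposite directions. Both footprints and TE rose in 35 genes and fell in 83.

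Against the authors' tables, the order of genes was close and the number of calls was not. TE changes had a Spearman correlation of 0.975 across 9432 genes, and the authors' table has 2092 genes under an FDR of 0.05 (926 raised, 1166 lowered), against 160 here and 819 with the tumour block. Of 158 genes called here that are in it, 144 were called by the authors with the same sign (91.1%; 94.9% at 0.1). Of 45 genes with raised TE here, 43 are in the authors' table and 29 were called there, while all 115 with lowered TE were. SIPA1L3 has an authors' TE change of 0.78 on the log2 scale (FDR 0.035) against 3.26 here, FOXO1 0.27 (FDR 0.52) against 1.95, and CARM1 0.15 (FDR 0.59) against 1.49 with the tumour block. For RNA, the Spearman correlation was 0.99995 over 13118 genes, and 218 of the 225 genes called here were among the 313 of the authors' DESeq2 table (148 raised, 165 lowered; 96.9% shared, 85.0% at 0.1).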

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

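Of 9544 genes, 681 changed in footprints. DESeq2 gave 418, of which 385 were shared. It was run with no low-count filter, and its own filter left 9902 of 15022 genes without an adjusted p. A further bound of a 2-fold change left 109, and unadjusted p under 0.05 gave 2112. Leaving out 1 library gave 185 to 726 (185 without vehicle library 1, 415 without vehicle library 3, 438 without zotatifin library 1). Other scalings, filters, limma-voom and thinned footprints gave 531 to 905, and a replicate block by number 796, of which 664 were shared. This block joins vehicle and zotatifin tumours of the same number, for which the correlations gave no clear sign of pairing. Its counts were therefore not taken as support here, in RNA or in TE.

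In RNA, 225 of 13118 genes changed. With no filter there were 624, and a replicate block by number gave 527, of which 222 were shared. A 2-fold bound left 56, and unadjusted p gave 2401. Leaving out 1 library gave 11 to 396. The number depends most on vehicle library 1 (11), vehicle library 3 (25) and zotatifin library 3 (48).

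For TE, 160 of 9454 genes changed. The replicate block by number gave 344 and the block by tumour 819, each with 159 of the 160. A 2-fold bound left 64, and unadjusted p gave 1446. Leaving out 1 tumour gave 56 to 132.

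Lists called by camera numbered 10 in footprints, 10 in RNA and 2 in TE. With an estimated correlation there were 0 in footprints, 0 in RNA and 0 in TE, and with fry also 0, 0 and 0. Leaving out 1 tumour gave 1 to 4 lists in TE. The correlation of footprint and RNA changes, 0.168, ran from 0.121 to 0.233 (without vehicle tumour 1 and without vehicle tumour 2).

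Among named genes, 34 of 74 footprint calls, 7 of 42 RNA calls and 13 of 30 TE calls held without any 1 library or tumour. No call came out with the opposite sign under any setting. A fit without a library or tumour has fewer samples and less power. A lost call therefore need not mean that 1 library made the change. Alternatives with 5′ UTR sequence were not run.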

Other observations

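In vehicle tumours, the gene lists differed widely in the ratio of footprints to RNA. That ratio was not corrected for coding or transcript length, so lists may differ in it without differing in translation. Reads of mouse cells were not removed, which may move the ratios of the marker lists. The median log2 ratio was 1.80 ± 0.11 (SD over 3 tumours) for replication-dependent histones, 1.43 ± 0.034 for proteasome subunits, 1.33 ± 0.12 for oxidative phosphorylation and 1.25 ± 0.058 for heat shock proteins, and each lay at the 100th percentile of 10000 random lists of the same size. Higher medians were found for myeloid markers (2.80 ± 0.28, 3 genes) and red blood cell markers (2.67 ± 0.25, 3 genes), at percentiles 98.8 and 95.7 of such lists. At the low end of the lists given here, reported eIF4A-dependent oncogenes, at −0.88 ± 0.13, lay at percentile 2.84 and ribosomal proteins, at −0.51 ± 0.10, at percentile 2.24.

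For the rise of TE, both tests were chosen after the result was seen. Fragments that are not footprints might raise the ratio of footprints to RNA. The 45 genes with raised TE had a median log2 ratio of −0.24 over the treatments. It lay within the −0.66 to 0.73 of 10000 random gene sets. Of the 45, 7 lay in the top 5% of the vehicle ratio, as did 11 of the 115 genes with lowered TE. This source therefore stays open. Footprints piled up at few positions stay open as well: the authors' estimate over the value here had a median of 0.898, with 13 of 43 genes under 0.5 (SIPA1L3, FOXO1 and CARM1 among them), but the authors' model is not described in the sources used here, so the ratio decides nothing.

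For the footprint rise of 67 genes that either did not pass the RNA filter (22) or lay in the top 5% of the vehicle ratio of footprints to RNA, both tests were chosen after the result was seen. The 22 include LOR, STUM and BOD1L2. Thinning all libraries to 838135 counts left the median log2 change at 0.59, against 0.58 at full depth, but thinning keeps the expected share of each gene, so it says nothing on the cause. A fixed amount of foreign fragments would weigh more in a shallow library, and it would give 0.62 between the treatments, near the 0.58 ± 0.048 (SE over genes) found. Within zotatifin, the shallowest less the deepest library gave 0.37 where 0.92 would follow, and within vehicle 0.055 where 0.37 would follow, but each of these sets 1 library against 1 other. The genes were chosen for their rise between the treatments, so the match there decides nothing. Both within-treatment values were lower than a fixed amount of foreign fragments alone would give. Whether foreign fragments are part or all of the rise is thus not decided. Bias by GC content was not tested and stays open too.

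For the fall of stromal markers, the test of the fibroblast list without single libraries was chosen before the result was seen and the others after it. Fewer host cells or reads in the zotatifin tumours would lower all markers, and median RNA log2 changes were −0.93 ± 0.37 (SE over genes) for fibroblast, −0.97 ± 0.89 for myeloid, −1.26 ± 0.28 for muscle and adipocyte and −0.32 ± 0.35 for red blood cell markers. Without 1 library, the values nearest to 0 were −0.81 for fibroblast (zotatifin library 3) and −0.36 for myeloid markers (vehicle library 3), so no single library decides the direction of these 2 lists. Camera did not call the muscle and adipocyte list (adjusted p = 0.47), which turned to 0.40 without vehicle library 2 (0.80) and was called without vehicle library 3 (5.9e-04), or the red blood cell list (0.21), which went to −0.064 without vehicle library 1 (0.51) and was called without vehicle library 2 (0.037). Fewer host cells may be a cause, but the lists do not decide it, and an effect of zotatifin on these genes stays open.

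The splits of the samples were chosen before the result was seen. There are 10 ways to divide 6 samples into 3 and 3, too few for a share under 0.05. In each comparison 1 split, the real one, had as many genes: 681 in footprints (highest other 0), 225 in RNA (highest other 2) and 160 in TE (highest other 0).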
